A study of Mus musculus with 9 samples.

How the data were processed

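The 9 samples were decidual tissue, the lining of the pregnant uterus, described by the labels as mouse. Control samples (n = 3) came from CBA/J × BALB/c matings, Model samples (n = 4) from CBA/J × DBA/2 matings described as a recurrent miscarriage model, and STW samples (n = 2) from the same mating as Model with a treatment called STW. The series title names Shoutai wan, a traditional Chinese herbal pill, and STW was taken to stand for it. Dose, route and gestational day are not given in the sources used here. Group and replicate number were taken from the sample titles. The labels do not say that the samples of a group came from separate animals, so p-values here measure only the spread between these samples, which may be technical.

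Per the labels' protocols, total RNA was extracted with Trizol, checked for integrity, enriched for mRNA with oligo(dT) beads, and made into strand-marked (dUTP) libraries whose adapters carried unique molecular identifiers, then sequenced as read pairs on an Illumina NovaSeq. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR were among the tools used, without their roles. Whether identical molecules were collapsed, how reads shared between gene copies were assigned, and which genome build and annotation were used is not given in the sources used here.

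The authors deposited 1 table of 22731 genes with whole-number counts and with FPKM (fragments scaled by gene length and library size) for each library, per the file headers. Its 9 count columns and 9 FPKM columns were used, and no other per-sample column was left over. The columns name the groups Con, Mod and Tre with a library number. Con was read as Control, Mod as Model and Tre as STW, the treated group, each with its number from the title. That Tre means STW rests on the meaning of the prefix. The ratio of count to FPKM was constant per gene up to 1 factor per library, with a median coefficient of variation of 0.0321% over 10976 well covered genes. All 22731 gene identifiers in the table were rat Ensembl identifiers and 0 were of another kind, although the labels give mouse. Among them 31 rows carried RT1 names, the rat name of the major histocompatibility complex. Gene symbols, identifiers and coordinates are therefore printed as the table gives them, the build of the coordinates is not given, and no reference genome was used with them. Where a symbol stood on more than 1 row (662 symbols), the row with the highest mean FPKM was named.

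The design fixed before the data were examined foresaw limma on log2(FPKM + 1) and, should counts be found, edgeR instead. Counts were found, so edgeR's quasi-likelihood test was the main test and the FPKM tests became alternatives. All 9 libraries entered 1 fit with group as the only term, after TMM scaling and filterByExpr, which kept 18151 genes (16425 protein-coding). R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0 were used, and matplotlib 3.10.9 drew the figures. Tests were two-sided, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no fold limit. Levels are CPM, counts scaled to a common library size with the TMM factors, given as mean ± SD over the libraries of a group. Log2 differences come from the fit, with a standard error of the log2 difference divided by the square root of F and a 95% interval from the same test. The fit left 6 residual degrees of freedom, and the common biological coefficient of variation was 0.525. Floors for genes without a count use 3 counts over all libraries of the group. These floors cover counting error only, while the 95% intervals also take in the spread between libraries.

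Gene lists for the tissue and the treatment (38 lists of decidual, placental, immune, vascular, muscle, epithelial, stress and metabolic genes) were fixed before the data were examined. They were written with mouse symbols and matched to the table's symbols without regard to case, so that genes named differently in rat stayed unmatched. Every row of the table held at least 1 count over the 9 libraries. A gene without any count would thus have no row either, and a missing row does not tell which applies. The 36 lists with at least 5 tested genes were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists. They were tested beside that with camera at an estimated correlation and with fry, which tests only whether a list's genes move on balance one way. Of the trophoblast giant cell list 3 of 24 genes were matched and 0 tested, and of the Y-linked list 2 genes were tested, so both went untested as lists. A list score per library, the mean log2(FPKM + 1) over genes with an FPKM of at least 1 in at least 2 libraries, was compared between groups by an exact two-sided permutation test for 33 lists.

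Genes were named by a rule fixed before the data were examined. In Model against Control and STW against Model, it took up to 8 genes each way past the test with at least a 2-fold difference and a mean FPKM of at least 5. Where fewer than 4 passed in a direction, it took the 4 with the smallest unadjusted p, called not past the test. It added up to 3 members of each list called by the set test, the fixed panel Pgr, Hand2, Bmp2, Prl8a2, Tpbpa, Afp, Ncr1 and Vegfa, and the 4 genes with the strongest opposite differences in both comparisons. In STW against Control it took only 4 genes each way. Other genes named were chosen after their values were seen, and are said to be.

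The edgeR test was checked on simulated counts drawn from the real libraries' means and sizes, with 200 changed genes in each of 3 runs per comparison. Of changed genes it recovered, at 2, 4, 8 and 16-fold, 5.33%, 53.3%, 76.0% and 90.0% in Model against Control (17743 genes per run), 2.67%, 50.0%, 73.3% and 89.3% in STW against Model (17728 genes), and 2.67%, 40.7%, 68.0% and 80.0% in STW against Control (17737 genes). No recovered gene had the wrong sign, and 9, 19 and 15 unchanged genes were called over all runs of the respective comparison. Changed genes were drawn from those with a mean of at least 1 CPM, and simulated libraries varied independently. The shares recovered therefore do not cover genes of lower level or trends shared between libraries.

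Libraries of a group were checked for double deposits by a chi-square comparison of their counts. The chi-square per degree of freedom lay between 179.7 (Model 3 and Model 4) and 644.1 (Control 1 and Control 2), so no pair agreed within sampling noise. Alternatives fixed beforehand were other filters, scalings, tools, pseudocounts, thresholds, a replicate block, fits of only 2 groups, and leaving out each library. Without STW 1 or STW 2 the STW group holds 1 library, which is then assumed to vary like the libraries of the other groups. Added after seeing the data were edgeR's newer dispersion setting, 2 surrogate variables from svaseq, leaving out Control 2 and STW 2 together, and camera with an estimated correlation under every other setting. For genes read off both Model comparisons, 50 simulations of unchanged groups gave the values that shared Model libraries produce. The correlation and the shares of signs were also computed for 100 assignments of the libraries to groups of the same sizes, chosen after seeing the data.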

Results

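Decidual transcriptomes were compared between 3 Control samples (CBA/J × BALB/c matings), 4 Model samples (CBA/J × DBA/2 matings, a cross used as a model of recurrent miscarriage) and 2 STW samples (the Model cross given STW). The father's strain differed between Control and the other groups by design. Total counts per library were 51574040, 49431354 and 49955984 in Control 1 to 3, then 49898330, 51936558, 48159486 and 52728696 in Model 1 to 4, and 47837977 and 48542501 in STW 1 and 2. Between 18725 and 19512 genes had a count in a library. All gene identifiers in the table were rat identifiers although the labels give mouse, and genes are given as the table names them.

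The libraries did not group by label. Across genes, log2 CPM correlated at 0.967 between Control 2 and STW 2, against 0.921 between Control 2 and Control 1 and 0.918 between STW 1 and STW 2. STW 1 correlated most with Model 2 (0.965), and so did Control 1 (0.964). The mean correlation was 0.9331 within groups and 0.9345 between groups. STW 2 and Control 2 also had the lowest TMM factors (0.895 and 0.902) and the highest mitochondrial mRNA shares, 8.07% and 5.67% of counts, against 3.98% to 5.43% in the other libraries. Smooth muscle list genes took 4.44% of counts in STW 2, 3.88% in Model 1 and 3.20% in Control 2, and 1.05% in Control 1. Trophoblast giant cell list genes took at most 4.07e-05% of counts in any library. Prl8a2, on the list of decidual stromal markers, and Tpbpa, a placental marker, were matched to no row and are not analysed here. A missing row does not tell a different name from a lack of counts.

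**Figure D1:**
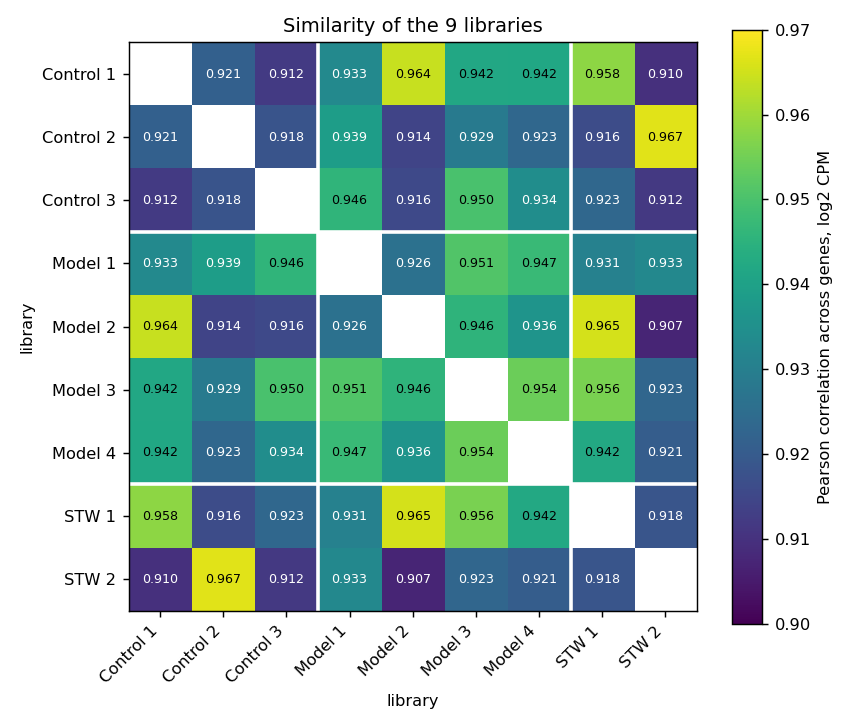
Pearson correlation of log2 CPM across 18151 genes for each pair of the 9 libraries (both axes list the libraries, white lines part the groups, and brighter cells are higher correlations). The brightest cell is Control 2 with STW 2 (0.967), and the darkest is Model 2 with STW 2 (0.907).

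The comparison of Model with Control asked how the decidua of the miscarriage cross differed from that of the other cross. The smallest unadjusted p belonged to Mt2A, a metallothionein that binds zinc and copper, at 99.6 ± 13.4 CPM in Model (SD, n = 4) and 43.0 ± 10.1 in Control (SD, n = 3), a log2 difference of 1.21 (SE 0.19, 95% interval 0.78 to 1.65). Rfk, the kinase that turns riboflavin into FMN, stood at 49.5 ± 3.84 in Model and 101.1 ± 23.5 in Control. Il17rb, a receptor chain for the cytokine IL-25, stood at 8.09 ± 1.74 and 76.9 ± 57.5, with a log2 difference of -3.25 (SE 0.60) and Control 3 at 143.3 (-2.43 without it). None of these passed the test: edgeR called 0 of 18151 genes in either direction (smallest adjusted p = 0.9997), with 416 genes at an unadjusted p under 0.05 where chance gives 908. Other splits of the Control and Model libraries had a median of 641.5 such genes. DESeq2 called 5 genes, 2 higher (Mt2A, Frmpd4) and 3 lower (Il17rb, Rfk and Sult1b1, the last named after its value was seen).

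Other genes of the rule showed smaller or more scattered differences. Pdgfc, a growth factor of the PDGF family, was at 117.6 ± 23.6 CPM in Model and 70.9 ± 10.1 in Control, a log2 difference of 0.73 (SE 0.20). The transcription factor gene Maz differed by 0.40 (SE 0.11) at 68.1 ± 3.93 against 51.5 ± 3.58. Alox15, a lipoxygenase, was at 28.3 ± 28.7 against 3.35 ± 0.863, with Model libraries from 5.27 to 66.6 (log2 difference 3.08, and 2.22 without Model 4). On the lower side, the aminopeptidase gene Xpnpep1 was at 107.2 ± 4.76 against 154.6 ± 14.0, a log2 difference of -0.53 (SE 0.13), and the nucleotidase gene Bpnt1 at 36.5 ± 6.96 against 72.6 ± 25.3, a log2 difference of -0.99 (SE 0.24). Of the fixed panel, Bmp2, a factor of decidualisation, was at 10.3 ± 2.97 against 6.18 ± 1.76, and the progesterone receptor gene Pgr at 75.8 ± 37.3 against 187.4 ± 202.5, where Control 2 alone held 415.7 (log2 difference -1.31, and 0.05 without Control 2). Hand2, another decidual regulator, differed by 0.22 (SE 0.27), Vegfa, the angiogenic factor, by 0.19 (SE 0.36), the NK cell receptor gene Ncr1 by -0.12 (SE 1.07), and the fetal liver gene Afp by 0.08 (SE 1.65). Afp had counts in Control 3 only among the Control libraries, at 1.47 CPM, against 0.308 to 0.652 in the 4 Model libraries, and without Control 3 it was at 0 counts in Control. In 593 genes (3.27%) the 2 groups did not overlap, where chance gives 5.71%. Mt2A lies on chromosome 19 at 11307967 to 11308740, Rfk on chromosome 1 at 236494221 to 236501733 and Il17rb on chromosome 16 at 6064288 to 6077978, with a build that is not given.

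As lists, 3 gene groups were lower in Model by camera, all tied to mitochondria or protein stress. With an estimated correlation all 3 calls were lost (adjusted p = 0.890 for each). All 12 mitochondrially encoded transcripts had negative log2 differences, with a median of -0.30 (adjusted p = 0.00259), among them Mt-nd5 at 1479 ± 209 CPM against 2011 ± 424, Mt-co2 at 4047 ± 632 against 5301 ± 1225 and Mt-nd2 at 2098 ± 265 against 2565 ± 249. Of the nuclear oxidative phosphorylation genes 24 of 28 were negative (median -0.14, adjusted p = 0.0260), with Cox5a at 72.9 ± 9.44 against 91.3 ± 16.8, Cycs, which encodes cytochrome c, at 113.8 ± 39.1 against 172.5 ± 39.2, and Sdhb at 79.7 ± 3.33 against 93.8 ± 14.1. Of the heat shock and unfolded protein response genes 21 of 25 were negative (median -0.19, adjusted p = 0.0260), with the chaperone gene Hspa8 at 1225 ± 137 against 1580 ± 485, Asns, which encodes asparagine synthetase, at 25.8 ± 7.73 against 39.1 ± 13.8, and Trib3, a stress-induced pseudokinase gene, at 0.806 ± 0.411 against 3.16 ± 4.32, with Control 1 at 8.13 (log2 difference -1.97, and 0.27 without Control 1). No member of these lists passed the test adjusted over the list alone or over all genes. Without Control 2, the Control library with the highest mitochondrial share, 2 other lists were called, uterine NK cells and T cells, both lower (adjusted p = 0.964 for each with an estimated correlation), and 0 of the 3 lists kept the call. Leaving out Control 1, Control 3, Model 1, Model 3 or STW 1 gave 12, 11, 8, 6 and 5 called lists, each time with these 3 among them, while without Model 2 or Model 4 only 1 of the 3 was called. With limma on quantile-normalised log2(FPKM + 1) 0 of the 3 were called, and 1 other list, ribosomal proteins, was higher. The ribosomal call too was lost with an estimated correlation.

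Immune and decidual lists did not pass in this comparison on unweighted log2 CPM of all 9 libraries with group as the only term. Other settings called immune lists. Of 23 uterine NK cell genes 19 were negative (median log2 difference -0.28, adjusted p = 0.493), and of 19 T cell genes 16 (median -0.49, adjusted p = 0.0603). T cell genes were called lower with library quality weights (adjusted p = 0.00791), and with limma on log2(FPKM + 1) (0.0359) or log2(FPKM + 5) (0.0220). They were so too with only Control and Model compared (0.0416) and without Model 2 (0.0319). These 5 calls were lost with an estimated correlation (adjusted p = 0.884, 0.944, 0.925, 0.906 and 0.971). Inflammatory cytokine and chemokine genes had a median of 0.38 with 20 of 32 positive (adjusted p = 0.369), and were called higher with the replicate number as a block (0.00355) and without Control 1 (0.0167). Both calls were lost with an estimated correlation (adjusted p = 0.969 and 0.803). Interferon response genes were negative in 18 of 26 (median -0.12), although the direction by camera was higher (adjusted p = 0.493). They were called higher with the block (0.0294) and without Control 1 (6.67e-10), and lower without Control 3 (0.0253). An estimated correlation ended these calls too (adjusted p = 0.969, 0.803 and 0.732). Decidual stromal markers were evenly parted, 9 positive and 9 negative (adjusted p = 0.369).

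The comparison of STW with Model asked what the treatment did within the miscarriage cross. Mt2A again had the smallest unadjusted p, now in the other direction, at 34.6 ± 3.12 CPM in STW (SD, n = 2) and 99.6 ± 13.4 in Model (SD, n = 4), a log2 difference of -1.52 (SE 0.23, 95% interval -2.04 to -1.01). Tp53inp2, a gene of autophagy, stood at 195.4 ± 17.3 against 111.6 ± 6.88, a log2 difference of 0.81 (SE 0.14). Cdc45, part of the replicative helicase, stood at 102.3 ± 13.8 against 41.0 ± 7.41, a log2 difference of 1.32 (SE 0.30). Csf3, which encodes the neutrophil growth factor G-CSF, stood at 0.326 ± 0.288 against 13.8 ± 11.9, with Model libraries from 1.001 to 29.6. None passed the test: edgeR called 0 of 18151 genes (smallest adjusted p = 0.850), with 962 at an unadjusted p under 0.05 where chance gives 908, and DESeq2 called 27, 7 higher and 20 lower.

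Among the other genes of the rule, Enpp5, a phosphodiesterase family member, was at 102.1 ± 17.2 CPM in STW and 51.8 ± 10.2 in Model (log2 difference 0.98, SE 0.21), and Ntmt1, an N-terminal methyltransferase gene, at 35.6 ± 4.07 and 20.4 ± 0.836 (0.80, SE 0.17). Lower in STW were the scaffold gene Tanc2, at 29.4 ± 1.55 and 46.2 ± 3.34 (-0.65, SE 0.15), Dtx4, a ubiquitin ligase gene of the Notch pathway, at 10.1 ± 2.52 and 25.0 ± 6.45 (-1.30, SE 0.30), and the unnamed locus AABR07033887, at 12.4 ± 0.493 and 27.6 ± 3.78 (-1.15, SE 0.27), with Model 1 apart at 33.2. In the panel, Pgr was at 27.6 in STW 1 and 258.6 in STW 2, against 75.8 ± 37.3 in Model. Ncr1 was at 2.42 in STW 1 and 0 in STW 2 against 4.89 ± 1.14, Vegfa at 139.1 ± 66.6 against 197.6 ± 66.3, Bmp2 at 8.87 ± 2.46 against 10.3 ± 2.97 and Hand2 at 11.4 ± 1.23 against 10.99 ± 1.65. Afp had 0 counts in both STW libraries against 0.521 ± 0.149 CPM in Model, at least 16.1-fold lower with a floor of 3 counts over the group. That bound covers counting error only, and the fit's 95% interval of the log2 difference, -15.51 to 0.079, included 0. The groups did not overlap in 2941 genes (16.2%), where chance gives 13.3%. Tp53inp2 lies on chromosome 3 at 150910398 to 150918525, Cdc45 on chromosome 11 at 86329012 to 86358453 and Csf3 on chromosome 10 at 86616785 to 86619157, in the table's coordinates.

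**Figure D2:**
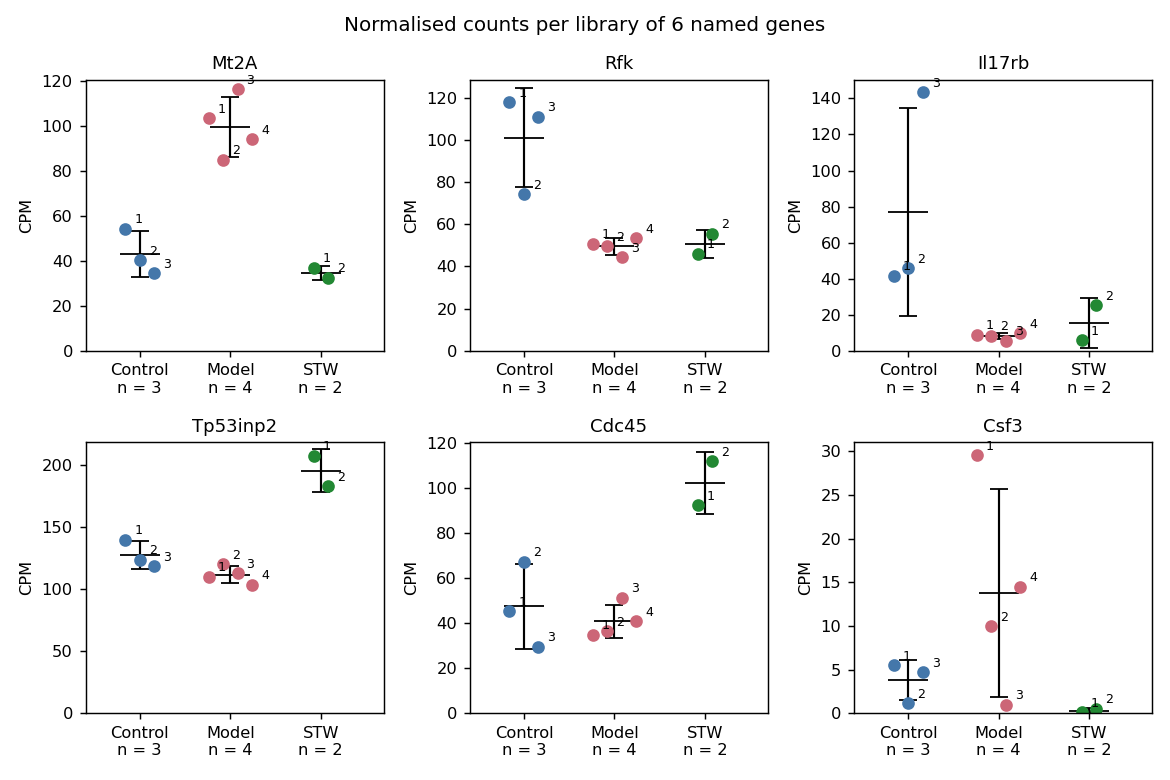
CPM of 6 named genes (vertical axes, from 0) in each library of the 3 groups (horizontal axes), with dots for libraries numbered by replicate, a long bar for the group mean and whiskers for 1 SD. All 4 Model libraries lie above every other library for Mt2A (lowest Model 84.9 CPM, highest other 54.1), while the Model libraries of Csf3 spread from 1.001 to 29.6.

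By camera 13 lists separated STW from Model, 7 higher and 6 lower in STW. With an estimated correlation all 13 calls were lost (adjusted p = 0.713 for each). Vascular genes had the smallest p among the higher lists: 25 of 28 endothelial and angiogenic genes were positive, with a median log2 difference of 0.63 (adjusted p = 1.86e-09). Among them Emcn, an endothelial sialomucin gene, was at 70.9 ± 24.9 CPM against 41.3 ± 6.09, Angpt2, a vessel-remodelling factor, at 37.1 ± 13.5 against 19.6 ± 4.75, and Esm1 at 17.1 in STW 2 but 0.795 in STW 1. By p respiratory genes followed, with 27 of 28 nuclear oxidative phosphorylation genes positive (median 0.33, adjusted p = 3.25e-08) and 12 of 12 mitochondrially encoded transcripts (median 0.71, adjusted p = 6.22e-08). Ndufa1 was at 45.02 ± 19.6 against 19.3 ± 6.31, with Model 1 apart from its group at 28.7, Ndufb9 at 90.3 ± 13.5 against 62.5 ± 7.81, and Sdhb at 101.4 ± 5.67 against 79.7 ± 3.33, with Model 1 apart at 84.7. Mt-nd1 was at 4934 ± 1624 against 2769 ± 306, Mt-nd4 at 3126 ± 1212 against 1744 ± 280 and Mt-nd6 at 854.2 ± 374.1 against 450.5 ± 96.8. STW 2 held the highest mitochondrial mRNA share of the 9 libraries.

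Proliferation, muscle, sterol and immediate early genes made up the other higher lists. Cell cycle and DNA replication genes were positive in 32 of 34 (median 0.43, adjusted p = 0.000234), with the replication genes Cdt1 at 10.6 ± 3.51 CPM against 5.47 ± 1.88, Mcm3 at 35.6 ± 3.93 against 22.6 ± 7.85 and Mcm6 at 51.3 ± 5.05 against 34.8 ± 11.3. Smooth muscle genes were positive in 18 of 19 (median 0.62, adjusted p = 0.0337), with the gap junction gene Gja1 at 196.4 ± 92.2 against 104.3 ± 24.6, the potassium channel gene Kcnmb1 at 26.4 in STW 1 and 70.2 in STW 2 against 21.4 ± 14.2, and the oxytocin receptor gene Oxtr at 43.0 in STW 2 and 0.306 in STW 1. Cholesterol and steroid genes were positive in 18 of 23 (median 0.69, adjusted p = 0.0392), with the lipoprotein receptor gene Scarb1 at 241.6 ± 47.9 against 166.9 ± 36.2, the sterol regulator Srebf1 at 72.0 ± 26.6 against 44.7 ± 5.21, and Hsd11b2, which inactivates glucocorticoids, at 1650 in STW 2 and 21.3 in STW 1. Immediate early genes were positive in 19 of 23 (median 1.15, adjusted p = 0.0177), with Dusp1 at 86.4 in STW 1 and 294.4 in STW 2 against 84.6 ± 12.7, Ccn2 at 106.5 ± 53.03 against 39.2 ± 25.1, and Ccn1 at 769.1 in STW 2 and 59.2 in STW 1. An estimated correlation ended all 4 calls (adjusted p = 0.713 for each), and with STW 1 as the lone STW library, taking its spread from the other groups, the immediate early list was called in the opposite direction, lower in STW (adjusted p = 0.948 with an estimated correlation). Without Model 2 the smooth muscle, cholesterol and immediate early calls were lost (adjusted p = 0.197, 0.1115 and 0.115), and without Model 3 the smooth muscle and cholesterol calls (0.110 and 0.102). The same happened without Model 4 to the smooth muscle and cell cycle calls (0.0708 and 0.0926), and without Control 1 to the cholesterol call (0.0527).

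The 6 lower lists were immune and epithelial. Of 23 uterine NK cell and cytotoxicity genes 19 were negative (median -0.96, adjusted p = 4.08e-06). The NK receptor gene Klrb1c was at 1.508 CPM in STW 1 and 0.530 in STW 2 against 2.69 ± 0.941 in Model. The transcription factor Eomes was at 0.835 in STW 1 and 0.0921 in STW 2 against 1.57 ± 0.509. Klre1 was at 0 counts in STW, at least 9.81-fold below the Model mean by counting error alone, with 0 counts in Model 2 also and up to 33 in the other Model libraries. The fit's 95% interval of its log2 difference, -14.45 to 0.44, included 0. Interferon response genes were negative in 24 of 26 (median -0.59, adjusted p = 0.00290), with the antiviral gene Rsad2 at 7.54 ± 0.208 against 33.7 ± 31.3 (log2 difference -2.16, and -1.31 without Model 1, which held 79.1), and the RNA sensor genes Ifih1 at 16.2 ± 1.40 against 30.6 ± 14.2, with Model 1 apart at 51.8, and Ddx58 at 13.8 ± 1.22 against 28.2 ± 10.9. T cell genes were negative in 15 of 19 (median -0.45, adjusted p = 0.00911), with Lck at 4.59 ± 1.25 against 7.41 ± 0.959 and Rorc at 8.05 ± 1.45 against 15.0 ± 4.20. Ikzf2 was at 1.976 in STW 1 and 0.806 in STW 2 against 2.66 ± 1.08. B and plasma cell genes were negative in 7 of 9 (median -0.66, adjusted p = 0.0186), with the antibody genes Ighm at 6.11 ± 3.00 against 13.6 ± 1.97 and Jchain at 2.099 in STW 1 and 0.4145 in STW 2 against 3.61 ± 1.12. Mzb1, a plasma cell gene with 0 counts in STW and 15 to 23 counts in each Model library, was at least 11-fold lower, and was the 1 gene of any called list that passed when adjusted over the list alone, against 0 over all genes. Epithelial and gland genes were negative in 16 of 18 (median -0.73, adjusted p = 0.00791). Cdh1, which encodes E-cadherin, was at 123.7 CPM in STW 1 and 57.3 in STW 2 against 178.7 ± 47.3 in Model. Ehf was at 19.3 ± 7.31 against 64.4 ± 48.6 with Model 4 apart at 136.9, and Pax8 at 20.1 ± 0.131 against 62.1 ± 61.0. Without Model 4, which held 151.8 CPM of Pax8, the log2 difference of Pax8 went from -1.63 to -0.68, and that of Ehf from -1.74 to -1.06. Inflammatory cytokine and chemokine genes were negative in 22 of 32 (median -0.84, or -0.80 with genes at 0 in a group put at their bound, adjusted p = 0.0310). Model 1 stood apart in this list's score, at 3.96 in mean log2(FPKM + 1) against 2.64 to 2.81 in the other Model libraries. STW 2, at 2.80, lay within those, and STW 1 was at 2.25. Besides Csf3, the neutrophil chemokine gene Cxcl2 was at 0.378 ± 0.247 against 2.699 ± 2.35 (log2 difference -2.83, and -2.04 without Model 1), while Il12b was higher, at 0.240 ± 0.209 against 0.0192 ± 0.0385, with counts in 1 Model library only. All 6 calls were lost with an estimated correlation (adjusted p = 0.713 for each). Without Model 1 the interferon, B cell and inflammatory calls were lost (adjusted p = 0.0903, 0.0903 and 0.232), and without Control 2 the inflammatory call (0.0551).

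The list calls differed between the 2 STW libraries. Leaving either out leaves 1 STW library, whose spread is taken from the other groups, so these fits compare that library with Model. Without STW 2 there were 4 calls, with 1 of the 13, inflammatory cytokines and chemokines, among them in the same direction. Without STW 1 there were 15, with the 12 others among them and the inflammatory list lost. Neither fit called a list with an estimated correlation (adjusted p = 0.948 for each of the 4, and 0.556 to 0.842 for the 15). A filter for a mean FPKM of at least 5 left 5 of the 13. Against 7 higher and 6 lower lists on log2 CPM, limma gave 7 and 3 on log2(FPKM + 1), 7 and 2 on log2(TPM + 1), and 3 and 4 on quantile-normalised log2(FPKM + 1). With the scores per library no list differed in any comparison by the exact permutation test, which cannot give a p below 0.0667 for 2 against 4 libraries, 0.0286 for 3 against 4 or 0.1 for 2 against 3. The smallest exact p were 0.0667, 0.143 and 0.2 in the same order, and adjusted over 33 lists 0.733, 0.972 and 0.990.

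**Figure D3:**
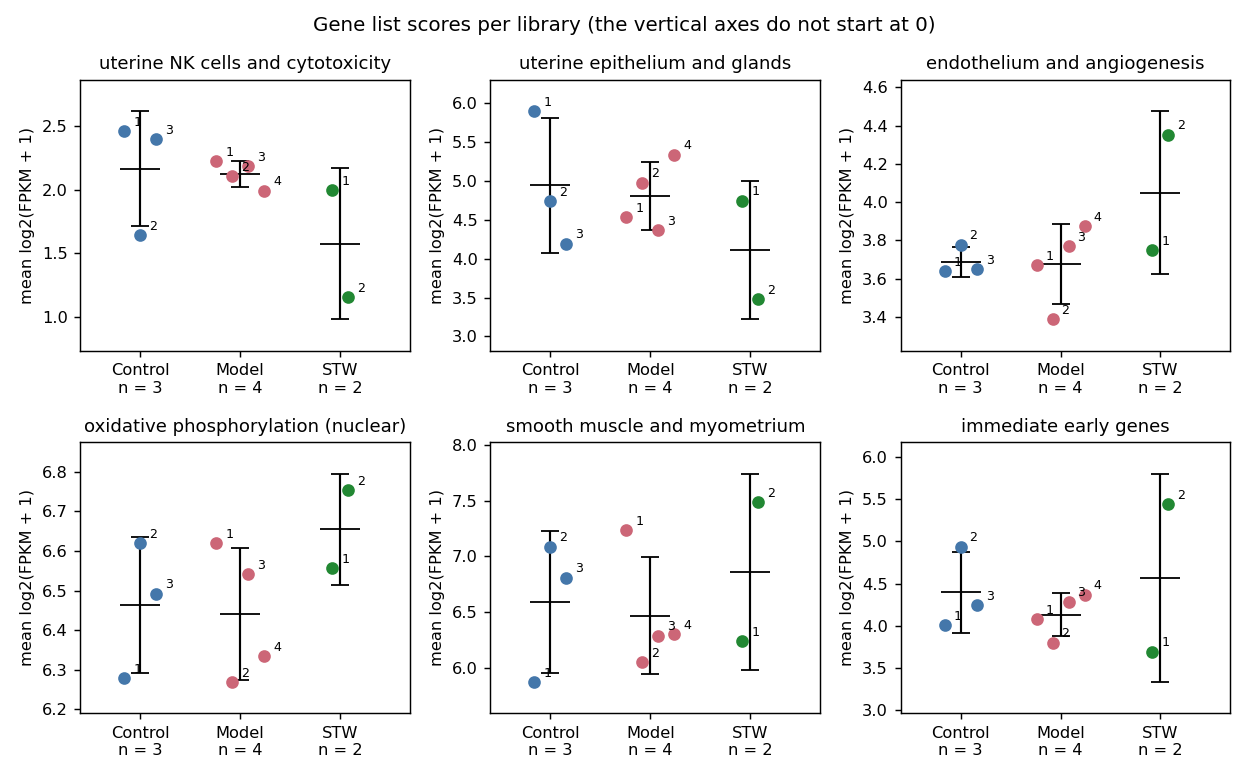
Score of 6 gene lists (mean log2(FPKM + 1), vertical axes not starting at 0) in each library of the 3 groups (horizontal axes), with dots for libraries numbered by replicate, a long bar for the mean and whiskers for 1 SD. The 2 STW libraries lie far apart: STW 2 has the lowest NK cell score (1.16) and the highest immediate early score (5.44), and STW 1 has 1.99 and 3.70.

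Whether STW returned genes changed in Model toward Control was read from both comparisons. Mt2A was the clearest case, at 43.0 ± 10.1 CPM in Control, 99.6 ± 13.4 in Model and 34.6 ± 3.12 in STW. The summed CPM of Mt2A and its copies Mt1 and Mt1m, which could share reads, was 55.4 ± 17.1, 122.3 ± 17.3 and 44.1 ± 8.15. Frmpd4, a scaffold protein gene, was at 0.317 ± 0.0976, 1.66 ± 0.595 and 0.203 ± 0.0589, on 7 to 132 counts per library. Sun3 had counts in Model only (0.226 to 0.958 CPM, highest in Model 4), at least 22.2-fold above Control and 13.9-fold above STW. Serpinb7 had counts in Control and STW but 0 in Model, at least 18.6-fold and 15.9-fold lower. Its STW mean rested mostly on STW 2, at 0.3915 CPM, with STW 1 at 0.0611 on 3 counts. No gene passed edgeR's test in both comparisons with opposite signs. At an unadjusted p under 0.05 in both there were 91 genes, 89 with opposite signs and 2 with the same sign. Independent lists would share 11 with opposite signs, a value that leaves out the Model libraries common to both comparisons. Of 100 assignments of the 9 libraries to groups of these sizes, the real one included, 56 had at least 89, and the median of the others was 122. DESeq2 called 2 genes both ways, Mt2A and Frmpd4.

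Both comparisons use the same Model libraries, which by itself makes their differences run opposite. Across 18151 genes, which are not independent replicates, the log2 differences correlated at -0.474, and 64.3% of genes had opposite signs. Simulated groups with no effect gave -0.378 (range -0.411 to -0.352) and 62.3% (range 61.7% to 63.1%), with independent libraries in every group. The real libraries were not independent in this way, since gene-centred values of Control 2 and STW 2 correlated at 0.544. In the 100 assignments of the real libraries, the real one included, the correlation was at least as negative in 37 (median of the others -0.3715) and the share of opposite signs at least as large in 47 (median of the others 62.1%). The covariance, to which shared libraries add the same amount with or without effects, was -0.195 against a simulated -0.178 (range -0.203 to -0.166), a difference of -0.0165, with the observed covariance inside the simulated range. With the Model libraries split so that each comparison used its own 2, the correlation lay between -0.144 and 0.00267 over 6 arrangements.

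The comparison of STW with Control set the treated miscarriage cross beside the other cross. Cxadr, which encodes a cell junction protein also used by viruses, stood at 4.61 ± 0.260 CPM in STW (SD, n = 2) and 17.1 ± 5.31 in Control (SD, n = 3), a log2 difference of -1.89 (SE 0.39, 95% interval -2.78 to -0.996). The RNA-binding protein genes Larp4b and Ptbp3 stood at 25.6 ± 3.58 against 50.7 ± 9.08 and at 41.5 ± 4.99 against 71.8 ± 8.88, and Gramd1b, a sterol transfer gene, at 15.0 ± 0.724 against 40.2 ± 8.65. On the higher side were Gata6, a transcription factor gene, at 28.7 ± 4.33 against 12.1 ± 1.06 (log2 difference 1.25, SE 0.28), Mmrn2, an endothelial matrix gene, at 110.1 ± 11.6 against 63.7 ± 2.64, and the unnamed loci AABR07070307, at 103.1 ± 10.9 against 63.4 ± 3.35, and AABR07054614, at 130.6 ± 15.0 against 68.3 ± 6.97. None passed edgeR's test, which called 0 of 18151 genes (smallest adjusted p = 0.987). There were 783 genes at an unadjusted p under 0.05 where chance gives 908, DESeq2 called 36, 8 higher and 28 lower, and the groups did not overlap in 2886 genes (15.9%) where chance gives 20%. Cxadr lies on chromosome 11 at 16826399 to 16873562 and Gata6 on chromosome 18 at 2416552 to 2446338.

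By camera 9 lists separated STW from Control, 4 higher and 5 lower (5 and 3 with limma on log2(TPM + 1), 5 and 4 with log2(FPKM + 1), and 3 and 6 with globin, mitochondrially encoded and fetal list genes left out). With an estimated correlation all 9 calls were lost (adjusted p = 0.887 for endothelial, decidual, NK, T cell and epithelial genes and 0.922 for the other 4). Higher were endothelial genes (24 of 28 positive, median 0.56, adjusted p = 1.63e-06), nuclear oxidative phosphorylation genes (25 of 28, median 0.25, adjusted p = 0.000498), mitochondrially encoded transcripts (12 of 12, median 0.40, adjusted p = 0.00387) and decidual stromal markers (13 of 18, median 0.38 and mean 0.05, adjusted p = 0.0198). Lower were NK cell genes (21 of 23 negative, median -1.21, adjusted p = 2.82e-07), T cell genes (17 of 19, median -0.98, adjusted p = 1.30e-05), epithelial genes (16 of 18, median -1.17, adjusted p = 0.000265), interferon response genes (26 of 26, median -0.67, adjusted p = 0.0194) and neutrophil genes (11 of 15, median -1.45, adjusted p = 0.0198). In mean log2(FPKM + 1) the interferon list scored 5.13 in Control 1 but 3.42 and 3.15 in Control 2 and 3, beside 3.70 and 3.27 in STW 1 and 2. The neutrophil list scored 3.95 in Control 1 but 1.92 and 1.95 in Control 2 and 3, beside 2.40 and 1.76. Without Control 1 neither was called (adjusted p = 0.233 for interferon, in the opposite direction, and 0.8895 for neutrophil genes). Mzb1, at least 12.8-fold lower with 0 counts in STW, passed adjusted over the list alone, although its B cell list did not pass (adjusted p = 0.0551). Without STW 2, the library with the highest mitochondrial share, 4 lists were called and 0 of the 9 kept the call, in a fit that compares STW 1 alone with Control and takes its spread from the other groups. Without STW 1 there were 16, and without Control 2 there were 14, both with all 9 among them, while without Control 1 there were 6, with the endothelial, NK and T cell lists of the 9 among them. The decidual, nuclear oxidative phosphorylation, epithelial and mitochondrially encoded lists were then also lost (adjusted p = 0.223, 0.223, 0.0652 and 0.0509).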

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

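In the Model group of 4 libraries, 120 results were checked for 1 library far from the others. They were the levels of named genes, the list scores, and library measures such as total counts and mitochondrial mRNA share. The measure was the gap between that library and its nearest neighbour, as a share of the group's whole range. Chance alone would mark about 6 of them, and 7 were marked, a number near chance. Groups of 2 or 3 libraries were not checked. Model 1 stood apart in 5 of the 7. These results are not independent, and whether they share an origin was not tested. Sdhb, a subunit gene of respiratory complex II, was at 84.7 CPM in Model 1 and 77.8 to 78.1 in the others (gap share 0.958). Ndufa1, of complex I, was at 28.7 against 15.6 to 17.1 (gap share 0.881). The RNA sensor gene Ifih1 was at 51.8 against 22.3 to 25.8 (gap share 0.880). The unnamed locus AABR07033887 was at 33.2 against 24.9 to 26.2 (gap share 0.835). The inflammatory cytokine and chemokine list scored 3.96 against 2.64 to 2.81 in mean log2(FPKM + 1) (gap share 0.872).

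The epithelial transcription factor gene Ehf was at 136.9 CPM in Model 4 and 33.2 to 44.0 in the other Model libraries (gap share 0.896). Il12b had counts in Model 3 only, at 0.0770 CPM (gap share 1), a level near the floor.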

How the results depend on the processing

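edgeR's newer dispersion setting, 2 surrogate variables, leaving out Control 2 and STW 2 together, and an estimated correlation under every other setting, were chosen after seeing the data, and all other alternatives before. The count of 0 genes past the threshold was the same in all 3 comparisons, and for genes changed back, under every edgeR and limma setting run at an adjusted threshold, a threshold of 0.1 and each left-out library (0 to 0) included. DESeq2 gave 5, 27 and 36 genes in Model against Control, STW against Model and STW against Control, and 2 changed back. An unadjusted p under 0.05 with a log2 difference of at least 1 gave 252, 434 and 350, and 70 changed back. The cause of DESeq2's higher counts was not tested. In the same order, edgeR's newer setting had 552, 1064 and 867 genes at an unadjusted p under 0.05, and the surrogate variables 846, 1003 and 1632.

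The set test moved more. Called lists in Model against Control (3) numbered 6 with limma on log2(FPKM + 1), 5 with log2(FPKM + 5), 1 with limma on quantile-normalised values, 7 with only the 2 groups compared, and 2 to 12 with a library left out. In STW against Model (13) they numbered 5 under the stricter filter, which tests fewer genes, 7 with limma on quantile-normalised values, 5 without Control 2 and STW 2, and 4 to 15 with a library left out. In STW against Control (9) they numbered 5 under the stricter filter and 4 to 16 with a library left out. An estimated correlation and fry gave 0 calls in each comparison (smallest adjusted p by fry 0.962, 0.499 and 0.942), and so did an estimated correlation under every other setting (smallest 0.508, 0.556 and 0.283). Median and z-score versions of the list scores also called 0. Causes other than fewer genes or libraries were not tested.

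With the replicate number as a block, 0 genes passed in each comparison and 6, 13 and 11 lists were called, keeping 1 of the 3, 9 of the 13 and 9 of the 9 calls made without it. Same-numbered libraries did not run together in all groups. Over 7 such pairs, deviations from the group means correlated between -0.340 (Model 1 and STW 1) and 0.595 (Control 2 and STW 2), with 3 above 0.1. Control 1 with STW 1 (0.483) also lay above every pair of unlike number (highest 0.430), while Model 2 with STW 2 was at -0.325. The deviations of the 2 STW libraries mirror each other, so these values are not independent and a batch shared by number is not excluded. Of the values of named genes under all alternatives, 2336 kept their direction and side of the threshold or moved by less than 1 SE, 20 passed only with DESeq2, 19 changed sign by more than 1 SE without passing, and 0 reversed past the threshold. The Oxtr, Hsd11b2, Ccn1 and Pgr signs in STW against Model changed without STW 2, with STW 1 as the only STW library. Depth was alike (47837977 to 52728696 counts), and for genes with 0 counts in a group it allows only bounds.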

Other observations

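Written before they were run were the tests of called genes and called lists in other splits and of the trends on the smooth muscle and immediate early scores. So were those of library similarity over all assignments and of Mt2A over 100 assignments. The closeness of Control 2 and STW 2 and the opposite differences of Mt2A had by then been picked from the data. All other tests and counts here, and the genes in the next paragraph, were chosen after their own values were seen.

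Some abundant transcripts were concentrated in 1 or 2 libraries regardless of group. S100g, which encodes a vitamin D-dependent calcium-binding protein, had 35575 counts in Control 2 and 42131 in STW 2, and 220 to 2456 elsewhere. Oxtr had 1518 and 1868 counts in the same 2 libraries and 15 to 167 elsewhere, and the hair keratin gene Krt85 had 13281 and 8898 against 15 to 103. The major histocompatibility gene RT1-N2 went the other way, with 0 counts in Control 2 and 4 in STW 2, and 451 to 2128 elsewhere. Control 3 alone held 25442 counts of Orm1, an acute-phase protein gene, against 12 to 244 elsewhere, and 21577 of Calca, the calcitonin gene, against 11 to 206. Model 2 alone held 9457 counts of the basal keratin gene Krt15, against 14 to 201. The egg coat gene Zp2 had 1608 counts in Model 2 and 1248 in Control 3, and 0 to 26 elsewhere. C3, a complement gene, ranged from 2209 counts in Control 3 to 445120 in Control 1.

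In Model against Control, chance cannot be excluded for the 3 called lists, since all 35 of the 35 splits of the 7 libraries called at least as many. The highest other split called 21 lists and the median of the others was 10.5. With an estimated correlation every split called 0, so the many calls were seen only in the test with the preset correlation of 0.01. The size of the correlation need not be the whole reason. Decidual stromal markers in STW against Control were estimated at 0.00827, below the preset value. Their camera p still rose from 0.00472 to 0.0287. In the real grouping the correlation was estimated at 0.89 for mitochondrially encoded, 0.628 for nuclear oxidative phosphorylation and 0.277 for heat shock genes. Whether a structure of the libraries other than their labels makes the genes of a list move together was not tested. For genes the real count was 0, which every split must reach, so their splits decide nothing (highest other 2). Genes at an unadjusted p under 0.05 numbered 416 in the real split. In the other splits they ran from 249 to 2173 with a median of 641.5. Of the 35 splits, the real one included, 28 had at least 416. STW, with 2 libraries, was not split, so the 13 lists called against Model and the 9 against Control have no such baseline. Chance cannot be excluded for them either.

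Control 2 and STW 2 resembled each other more than their own groups: gene-centred values correlated at 0.544. Both carry the same replicate number, and a batch shared by number is not excluded. Of the 1260 assignments of the 9 libraries to groups of these sizes, 693 had as large a gap between within-group and between-group correlation as the real one (-0.00139, highest other 0.0272), so a part played by the study groups was not seen, though groups this small leave it open and a mislabelled sample was not tested. Differing amounts of smooth muscle, or of immediate early expression set by handling time, may be a source: removing each gene's trend on the list score took the correlation to -0.0679 and -0.612. Random lists matched in expression also took it below 0.2 in 40.4% and 35.4% of 1000 draws, and as low as the lists did in 23.0% and 3.3%. The immediate early score thus followed these 2 libraries more closely than most lists, at 0.852 and 1.40 against at most -0.0185 elsewhere, but the bound set beforehand was met by many random lists, so neither source can be told apart from other trends shared by these 2 libraries.

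Mt2A was higher in every Model library than in any other, before and after summing with its copies. Reads shared between metallothionein copies are argued against, because the lowest Model library was 1.43 times the highest Control or STW library in the summed CPM. Chance stays open: 18 of 100 assignments of the 9 libraries, the real one included, held a gene with opposite signs at least as extreme in both comparisons, with up to 15 such genes in another assignment. Genes with opposite signs at an unadjusted p under 0.05 in both numbered 89, against a median of 122 and up to 1692 in the other assignments. The cross, with its different father, and the treatment remain open and untested as explanations.

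All gene identifiers were rat identifiers in a table whose labels give mouse. Mouse reads counted on a rat annotation could lose fast-changing genes and misplace copies, while rat tissue would make the labels wrong. The lowest mitochondrial mRNA share of a library, 3.98%, cannot separate these, because the loss of mouse mitochondrial reads on a rat genome is not known here. Either way, the tests compared libraries counted in 1 way, and names and coordinates hold only as the table gives them.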
